A study of Mus musculus with 8 samples.

How the data were processed

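Gene expression was measured by RNA sequencing in primary mouse lung fibroblasts that were left untreated or given recombinant TWEAK at 10, 30 or 100 ng/ml for 48 hours. Each of the 4 groups held 2 libraries, 8 in all, and groups and replicate numbers were taken from the sample titles. The labels do not say whether the 2 libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

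The authors deposited 1 table of raw counts, whole numbers of reads per gene row, with no normalization. The mm10 genome build, STAR and StringTie are named in the submitters' processing notes, per the labels, without versions or the step each was used for. The counting program, the annotation and whether strand was used are not given in the sources used here. Reads of overlapping or antisense genes could therefore be assigned to either partner, and reads of near-identical genes could be split.

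The table had 55335 rows. Rows without a gene symbol numbered 3225 and held between 0.168% and 0.178% of the counts of a library, and they were kept out of the library sizes and tests of the report. They were tested in a separate fit that held all rows. A further 80 symbols stood on more than 1 row, 160 rows in all. These rows were kept apart, and the row with the most counts carried the plain symbol. The symbols of 26 rows had been turned into dates, and none of these is named. Total counts ranged from 37345575 to 50896445 per library, so that 3 counts corresponded to between 0.0599 and 0.0801 CPM, the count scaled to a common library total.

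Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr by group, which left 17360 genes, and libraries were scaled by TMM. All 8 libraries entered 1 fit with a mean per group, with 4 residual degrees of freedom and 3.77 prior degrees of freedom. Each dose, and the mean of the 3 doses, was compared with untreated cells, and the doses were compared with each other, 7 contrasts in all. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors (SE) of log2 changes were obtained from the change and its F statistic and are approximate. Levels are TMM-scaled CPM, as mean ± SD of 2 libraries. Folds against untreated libraries with 0 counts are lower bounds against 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% counting interval, which covers counting error only.

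Gene lists for 19 pathways and functions, and 7 lists of markers of other cell types, were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. Pathway lists were tested with camera of limma 3.58.1 on voom values, with an inter-gene correlation preset at 0.01, adjusted over the 19 lists within a contrast. The same test with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, served as alternatives. Marker lists were adjusted separately, and the lymphocyte and red blood cell lists had no member past the filter.

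Genes were named by rule. Tnfsf12 and Tnfrsf12a were always named. For each contrast with untreated cells, the 10 largest rises and 10 largest falls were taken among called genes with a mean of at least 5 CPM over the 8 libraries and no overlap in CPM between the sides, leaving out symbols of predicted genes. Between doses, up to 5 rises and 5 falls were taken in the same way. From each pathway list, up to 4 members with the smallest p at 100 ng/ml were named. Members of the marker lists are named as markers. Not every gene the rule names is reported here.

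Gene positions are those of GENCODE M21 on the mm10 assembly, counted from 1. Of the tested genes, 16812 (96.8%) matched 1 annotated gene by symbol. Of the 114 genes named by rule 113 had a position, and 33 of them had an exon overlapping an exon of another gene, which makes their counts uncertain.

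The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, library totals without TMM, no low-count filter, a mean of at least 1 CPM, a fit of only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. When a library was left out, the lone library of its group was assumed to vary like the others. Further alternatives were chosen after seeing the data: thinning all libraries to the lowest total, leaving out genes whose replicates differed over 2-fold, and leaving out both libraries labelled 100 ng/ml.

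The tests were checked on simulated counts drawn from the real means, library sizes and dispersions, with 65, 64 and 59 of the genes tested changed by a small, a middle and a large fold. In the simulated comparison of 10 ng/ml with untreated cells, run on 16926 genes, 9.2% of genes changed 1.5-fold, 60.9% of those changed 2-fold and 66.1% of those changed 4-fold were recovered, and 3 unchanged genes were called. Among genes with at least 5 CPM, the recovered shares were 14.6%, 84.8% and 100%. In the simulated comparison of 100 ng/ml with untreated cells, 0% of genes changed 1.22-fold, 1.6% of genes changed 1.41-fold and 35.6% of genes changed 2-fold were recovered, with 4 unchanged genes called. In that of 30 ng/ml the shares were 6.2%, 59.4% and 64.4% at 1.5-, 2- and 4-fold, with 7 unchanged genes called, and in that of 100 against 10 ng/ml 0%, 0% and 39% at 1.22-, 1.41- and 2-fold with 1 unchanged gene called, each on 16926 genes. A simulated list of changed genes was called by camera with either correlation and by fry, and 0 of 18 unchanged lists were. Genes were drawn independently and lists at random in this check, so it does not test lists whose genes vary together. It also changed far fewer genes than the 5075 and 4041 called at 10 and 30 ng/ml in the real data. The Benjamini-Hochberg adjustment is less strict when more genes change. The recovered shares may therefore be too low for comparisons with many called genes.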

Results

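RNA was sequenced from primary fibroblasts of mouse lung after 48 hours with recombinant TWEAK, a cytokine of the TNF superfamily encoded by Tnfsf12, or without it. The design asked how the cells respond to 10, 30 and 100 ng/ml. There were 2 libraries per group and 8 in all, with total counts between 37345575 and 50896445. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 23.6 to 29.1, so none was counted as a duplicate. The first principal component of log2 CPM held 49.7% of the variance. On it the untreated libraries lay at -67.56 and -66.54, those labelled 100 ng/ml at -36.19 and -37.71, those labelled 30 ng/ml at 48.66 and 35.34, and those labelled 10 ng/ml at 61.44 and 62.57. Groups and doses are given as labelled throughout.

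At 10 ng/ml, several genes barely detected in untreated cells were abundant. Mmp9, a gelatinase that degrades matrix, rose from 0.16 ± 0.0278 to 359 ± 30.6 CPM (SD, n = 2), a log2 change of 11.10 ± 0.25 (SE, edgeR adjusted p = 6.82e-07). Spib, an Ets-family transcription factor, rose from 0.381 ± 0.256 to 291 ± 14.5 CPM (log2 change 9.57 ± 0.30, edgeR adjusted p = 2.15e-06). Madcam1, an adhesion molecule that binds lymphocytes, rose from 0.0799 ± 0.113 to 60 ± 2.89 CPM (log2 change 9.50 ± 0.47, edgeR adjusted p = 7.65e-06). Madcam1 had 8 counts in the untreated libraries, and its fitted change was 14.32 without untreated replicate 1. The matrix proteoglycan genes Ogn and Aspn fell, Ogn from 584 ± 11.7 to 16.9 ± 3.09 CPM and Aspn from 18.4 ± 0.424 to 0.618 ± 0.146 CPM, log2 changes of -5.11 ± 0.23 and -4.90 ± 0.20.

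The other large rises at 10 ng/ml were Traf1, an adaptor of TNF receptors, Ccl5, a chemokine, Bst1, Il4i1, Colq, Slc39a4 and Myh15. Traf1 had 3 counts in untreated cells, and its level was 1460 times higher, with a 95% counting interval from 498 to 7060. Myh15 had 0 counts in untreated cells and was at least 910-fold higher. Ccl5 rose by 7.43 ± 0.32 and Bst1 by 9.03 ± 0.85 on the log2 scale. Fitted changes from so few untreated counts moved when 1 library was left out, to 13.84 for Bst1 without untreated replicate 2 and, without untreated replicate 1, to 13.02 for Colq (7.15 in all libraries) and 12.01 for Slc39a4 (6.74). Besides Ogn and Aspn, the largest falls were those of Ces1g, a carboxylesterase (-5.30 ± 0.39), St8sia2 (-4.97 ± 0.39), Clec3b (-4.89 ± 0.36), Lrp4 (-4.68 ± 0.24), Gucy1a3 (-4.62 ± 0.21), Prss35 (-4.42 ± 0.28), Selenbp1 (-4.36 ± 0.15) and Sfrp2, a secreted Wnt antagonist (-4.31 ± 0.18). On mm10, Mmp9 lies on chromosome 2 from 164940780 to 164955850, Spib on chromosome 7 from 44525993 to 44532071 and Madcam1 on chromosome 10 from 79664559 to 79668537. Aspn (49544443 to 49567565) and Ogn (49608046 to 49624501) lie near each other on chromosome 13. Exons of Aspn, Bst1, Colq, Il4i1 and Sfrp2 overlap those of another gene, so their counts are uncertain. The same holds for Nfkb2, Itga8, Timp3, Cd34, Tnfsf12, H2-Q4, Lama2, Loxl2, Top2a, Ltbp2, Usp18, Plagl1, Acss3, Il2rg, Il34, Cxcl16, Gbp7, Ube2c, Pcdhb22, Pcdhga2, Pcdhgb1, Chmp3, Matr3, Mylk and Hopx among the genes named further on. Tnfrsf12a, the receptor of TWEAK, rose by 0.77 ± 0.15 (edgeR adjusted p = 0.00536), and Tnfsf12 itself fell by 0.45 ± 0.11 (edgeR adjusted p = 0.0171), on the log2 scale. The call on Tnfsf12 was lost without untreated replicate 1 (adjusted p = 0.0726), untreated replicate 2 (0.0739) or TWEAK10 replicate 2 (0.0901). In all, 5075 of 17360 genes changed at 10 ng/ml, 2610 higher and 2465 lower.

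**Figure D1:**
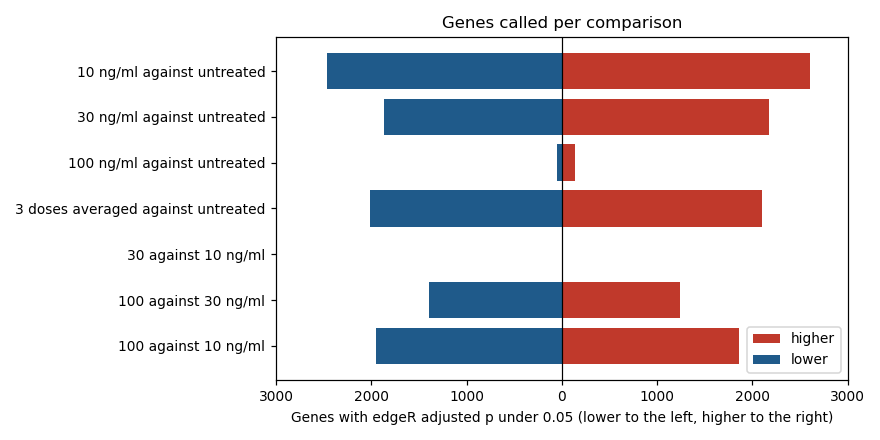
Horizontal bars give the number of genes with an edgeR adjusted p under 0.05 in each comparison, higher to the right and lower to the left of 0. The comparison of 10 ng/ml with untreated cells had 2610 genes higher and 2465 lower, that of 100 ng/ml 141 and 53, and that of 30 with 10 ng/ml had 0.

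Inflammatory gene lists rose at 10 ng/ml. Of 30 genes of the NF-kB pathway, 19 rose and 1 fell, and adjusted over the list alone 21 rose and 1 fell (camera adjusted p = 4.8e-11, adjusted p = 0.085 with an estimated correlation). Nfkb2 rose from 60.4 ± 1.55 to 415 ± 9.98 CPM, Birc3 by 2.09 ± 0.09 and Nfkbie by 3.64 ± 0.16 on the log2 scale. Of 20 chemokines 11 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.25 with an estimated correlation), with Ccl2 rising from 105 ± 18.9 to 1152 ± 66.7 CPM. Of 20 cytokines and haematopoietic growth factors 11 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.00256, adjusted p = 0.15 with an estimated correlation). Il33, an alarmin, rose by 3.43 ± 0.13 and Tnfsf11 by 2.63 ± 0.20, while Tnfsf15 fell by 2.55 ± 0.23 on the log2 scale. Of 24 genes of class I antigen presentation 15 rose, or 17 adjusted over the list alone, and none fell (camera adjusted p = 3.85e-08, adjusted p = 0.17 with an estimated correlation). H2-D1 rose by 1.18 ± 0.09 and H2-Q4 by 1.91 ± 0.12, and counts of such related genes may share reads. Of 18 TNF superfamily genes 10 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.00255, adjusted p = 0.085 with an estimated correlation), with Tnfrsf9 rising by 2.36 ± 0.19 and Fas by 1.62 ± 0.17.

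Matrix and fibroblast identity lists fell at 10 ng/ml. Of 40 fibrillar collagen and matrix genes 30 fell and 7 rose, the same adjusted over the list alone (camera adjusted p = 2.37e-09, adjusted p = 0.17 with an estimated correlation). Lama2 fell by 1.77 ± 0.11 and Lamc1 by 0.64 ± 0.05, while Col5a3 rose by 1.79 ± 0.09 and Col12a1 by 0.92 ± 0.07 on the log2 scale. Of 22 genes of collagen processing 11 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.00531, adjusted p = 0.25 with an estimated correlation), Loxl2 and Adamts2 among the falls (-1.49 ± 0.08 and -1.71 ± 0.09) and Adamts14 among the rises (2.39 ± 0.14). Of 33 lung fibroblast identity genes 20 fell, or 22 adjusted over the list alone, and 6 rose in both (camera adjusted p = 9.13e-05, adjusted p = 0.059 with an estimated correlation). Itga8, an integrin of alveolar fibroblasts, fell from 207 ± 7.77 to 24.5 ± 1.3 CPM, and Cd34, also on the list, rose from 2.11 ± 0.149 to 48.5 ± 4.57 CPM. Of 31 TGF-beta genes 15 fell and 7 rose, the same adjusted over the list alone (camera adjusted p = 0.0438, adjusted p = 0.25 with an estimated correlation). Tgfbr2 fell by 1.39 ± 0.08 and Nox4 by 2.21 ± 0.12, while Ltbp2 rose by 2.03 ± 0.04. Of 40 interferon-stimulated genes 15 fell, or 17 adjusted over the list alone, and none rose (camera adjusted p = 7.7e-05, adjusted p = 0.43 with an estimated correlation), Ifit2 by 1.71 ± 0.12 and Usp18 by 1.38 ± 0.28 on the log2 scale. The call on Usp18 was lost without TWEAK10 replicate 1 (adjusted p = 0.0503).

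Cell cycle and metabolic lists rose. Of 43 cell cycle genes 39 rose and none fell, the same adjusted over the list alone (camera adjusted p = 2.84e-16, adjusted p = 0.085 with an estimated correlation), with Top2a rising from 28.1 ± 2.48 to 73.7 ± 3.37 CPM. Of 25 p53 and growth arrest genes 15 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 2.32e-06, adjusted p = 0.053 with an estimated correlation). The cyclin-dependent kinase inhibitors Cdkn2a (2.28 ± 0.15) and Cdkn2b (1.84 ± 0.10) and the kinase Plk2 (2.24 ± 0.07) were among the rises. Of 27 oxidative stress genes 18 rose and 4 fell, or 20 and 4 adjusted over the list alone (camera adjusted p = 3.58e-07, adjusted p = 0.085 with an estimated correlation), with the cystine transporter Slc7a11 rising by 4.43 ± 0.16 and Hmox1 by 1.59 ± 0.06. Of 26 glycolysis and hypoxia genes 18 rose and 1 fell, or 20 and 1 adjusted over the list alone (camera adjusted p = 2.42e-09, adjusted p = 0.053 with an estimated correlation), Pgk1 by 1.16 ± 0.07. Of 23 genes of the unfolded protein response 10 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00256, adjusted p = 0.085 with an estimated correlation), and of 25 cholesterol genes 8 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00678, adjusted p = 0.17 with an estimated correlation). The lists not called by camera at 10 ng/ml were complement and acute phase with 2 of 18 higher and 7 lower (adjusted p = 0.093), myofibroblast and contractile with 9 of 29 higher and 14 lower (adjusted p = 0.205), and matrix proteases and inhibitors with 10 of 33 higher and 12 lower (adjusted p = 0.236). Adjusted over the list alone these were 3 and 7, 9 and 14, and 10 and 13. The protease list had a median log2 change of -0.02 and a mean of 0.15, and camera gave it a lower direction. Within the last list, Mmp10 rose by 3.15 ± 0.10 and Timp3, an inhibitor of matrix proteases, fell from 1584 ± 36.3 to 200 ± 13.5 CPM. C3 of the complement list rose from 1075 ± 36.8 to 5856 ± 41.4 CPM. Camera called 16 of the 19 lists, and 0 with an estimated correlation. Fry called the protease list (adjusted p = 0.00013) and not the interferon-stimulated one (0.096), and otherwise the lists camera called.

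**Figure D2:**
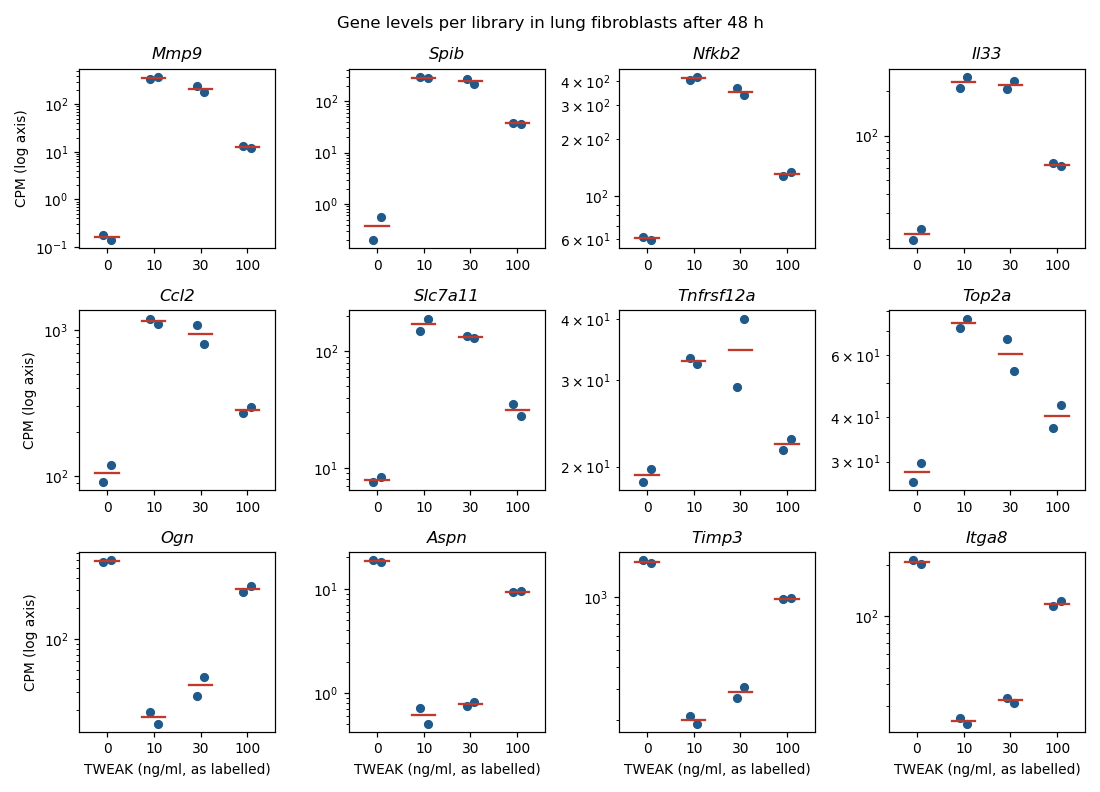
CPM of 12 genes on log axes, against the labelled dose in ng/ml, with a point per library (n = 2 per group) and a red line at the group mean. Mmp9 stood at 0.16 CPM without TWEAK, 359 at 10, 214 at 30 and 12.5 at 100 ng/ml, and Ogn at 584, 16.9, 34.8 and 310.5 CPM.

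At 30 ng/ml, the leading rises were those named at 10 ng/ml. Mmp9 rose to 214 ± 45.6 CPM (log2 change 10.36 ± 0.24, edgeR adjusted p = 1.37e-06), Spib to 249 ± 38.4 CPM, Madcam1 to 45.3 ± 9.71 CPM and Ccl5 to 32.2 ± 11.8 CPM. Myh15 was at least 529-fold higher. The fitted log2 change of Madcam1, 9.09, was 13.91 without untreated replicate 1. Among the falls, Aspn changed by -4.55 ± 0.19, St8sia2 by -4.23 ± 0.37, Ogn by -4.07 ± 0.21, Ces1g by -3.65 ± 0.35, Plagl1, an imprinted zinc finger gene, by -3.60 ± 0.18 and Acss3 by -3.48 ± 0.33 on the log2 scale. Tnfrsf12a rose by 0.85 ± 0.15 (edgeR adjusted p = 0.00422) and Tnfsf12 fell by 0.40 ± 0.11 (edgeR adjusted p = 0.0315). The latter call was lost without untreated replicate 1 (adjusted p = 0.118), untreated replicate 2 (0.122) or TWEAK30 replicate 1 (0.179). Camera called 15 of the 19 lists, 11 up and 4 down, while fry called the protease list (adjusted p = 0.00025) and not the interferon-stimulated one (0.42). Glycolysis and hypoxia (19 of 26 higher) and p53 and growth arrest (15 of 25 higher) held with an estimated correlation, both at adjusted p = 0.046. Of the interferon-stimulated genes 1 rose and 4 fell of 40 (camera adjusted p = 0.0289, adjusted p = 0.69 with an estimated correlation). Adjusted over the list alone, 1 rose and 3 fell, and the mean log2 CPM of the list was 4.33 and 3.53 in the 2 libraries of this group. In all 4041 genes changed, 2179 higher and 1862 lower. The number fell to 2540 without untreated replicate 1, 2661 without untreated replicate 2 and 2622 without TWEAK30 replicate 1.

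In the libraries labelled 100 ng/ml, Spib, Mmp9, Traf1, Madcam1 and Ccl5 were among the leading rises, as at 10 ng/ml. By the naming rule, which takes called genes only, Aspn was the only leading fall of both doses. The other leading falls at 10 ng/ml also had lower fitted levels at 100 ng/ml. They ran from 0.456 (St8sia2) to 0.702 (Prss35, 95% interval up to 1.01) times untreated, with 0.507 for Aspn. Spib rose from 0.381 ± 0.256 to 37 ± 0.143 CPM (log2 change 6.59 ± 0.29, edgeR adjusted p = 0.00012), Mmp9 to 12.5 ± 0.982 CPM (6.26 ± 0.24, edgeR adjusted p = 0.00012) and Madcam1 to 2.78 ± 0.151 CPM (5.07 ± 0.53, edgeR adjusted p = 0.00505). The fitted changes of Madcam1 and Traf1 were 9.89 and 9.95 without untreated replicate 1. C1s2, a complement protease gene, rose by 3.52 ± 0.24, Ccl5 by 2.88 ± 0.35, Pdlim4 by 2.83 ± 0.26, Pcdhb22 by 2.52 ± 0.21, Slamf8 by 2.48 ± 0.31 and Il2rg by 2.04 ± 0.28. Traf1 was 96.9 times higher, with a 95% counting interval from 32.7 to 473. The falls were those of Dhrs3, a retinoid-metabolising enzyme (-1.39 ± 0.16), Tnfsf15 (-1.32 ± 0.21), Mlana (-1.12 ± 0.17), Fmo2 (-1.10 ± 0.13), Igfbp5 (-1.07 ± 0.10), Cmklr1 (-1.06 ± 0.11), Gabra3 (-1.02 ± 0.11), Aspn (-0.98 ± 0.16), Shisa5 (-0.95 ± 0.10) and Pcdhgb1 (-4.17 ± 0.73), whose exons overlap those of many protocadherin genes and whose 2 untreated libraries differed 3.14-fold. The fitted changes of Pcdhb22 and Shisa5 were 2.25 and -0.19 at 10 ng/ml, and the difference between these doses passed the test for Shisa5 (edgeR adjusted p = 0.00148) but not for Pcdhb22 (0.369) or Pcdhgb1 (0.0813). The change of Pcdhgb1 at 10 ng/ml was -2.23 (edgeR adjusted p = 0.0394), but -1.18 without untreated replicate 1 (adjusted p = 0.249) and -3.52 without TWEAK10 replicate 1, and its call was lost without any 1 of 6 libraries. Tnfrsf12a stood at 22.2 ± 0.812 CPM against 19.2 ± 0.796 (log2 change 0.21 ± 0.15, edgeR adjusted p = 0.644) and Tnfsf12 at 33.6 ± 3.29 against 33.5 ± 0.161 CPM. Of the 50 genes named by rule and called at 100 ng/ml, 24 kept the call whichever library was left out, among them Spib, Mmp9, Madcam1, Traf1, C1s2, Pdlim4, Pcdhb22, Igfbp5, Cmklr1 and Shisa5. The call was lost for 25 without untreated replicate 1, 16 without untreated replicate 2, 21 without TWEAK100 replicate 1, 17 without TWEAK100 replicate 2, 7 without TWEAK10 replicate 1 or replicate 2 and 4 without TWEAK30 replicate 1 or replicate 2, with edgeR adjusted p between 0.0509 and 0.258. Ccl5, Slamf8, Il2rg, Dhrs3, Tnfsf15, Mlana, Fmo2, Gabra3, Aspn and Pcdhgb1 were among these. In all 194 genes changed, 141 higher and 53 lower, and DESeq2 called 598. The higher genes made up 72.7% of the calls, against 52.6% by limma-voom, which called 192 genes and shared 145 of the 194, and 55% with only the groups compared, which called 180 and shared 121. The number fell to 91 (79 higher and 12 lower) without untreated replicate 1, 116 without untreated replicate 2, 106 without TWEAK100 replicate 1 and 125 without TWEAK100 replicate 2.

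Camera called 13 of the 19 lists at 100 ng/ml, 9 up and 4 down, and 0 with an estimated correlation. Fry called 10, namely 8 of those 9, the TNF superfamily list, also up (adjusted p = 0.039), and the lung fibroblast identity list, down. It did not call class I antigen presentation (adjusted p = 0.42). Cytokines had 4 of 20 members higher and 1 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 3.99e-06, adjusted p = 0.087 with an estimated correlation), with Il33 rising by 1.57 ± 0.12, Il34 by 1.47 ± 0.16 and Tnfsf11 by 1.68 ± 0.20. Chemokines had 5 of 20 higher, or 7 adjusted over the list alone (camera adjusted p = 4.42e-06, adjusted p = 0.15 with an estimated correlation), with Ccl2 rising by 1.43 ± 0.16, Ccl7 by 1.34 ± 0.13, Ccl8 by 1.05 ± 0.07 and Cxcl16 by 0.79 ± 0.07. The NF-kB list had 6 of 30 higher, or 11 adjusted over the list alone (camera adjusted p = 2.37e-06, adjusted p = 0.15 with an estimated correlation), Nfkb2 by 1.12 ± 0.07. The oxidative stress list had 6 of 27 higher, or 12 and 1 lower adjusted over the list alone (camera adjusted p = 5.55e-09, adjusted p = 0.087 with an estimated correlation), Slc7a11 by 2.00 ± 0.15, Nqo1 by 0.76 ± 0.10, Hmox1 by 0.51 ± 0.06 and Prdx1 by 0.46 ± 0.06. The calls on Tnfsf11, Nqo1, Hmox1 and Prdx1 were among those lost when 1 library was left out. The cell cycle list had 1 of 43 higher, or 7 adjusted over the list alone (camera adjusted p = 7.55e-10, adjusted p = 0.15 with an estimated correlation), namely Ube2c by 1.04 ± 0.18, a call lost without any 1 of the 8 libraries. The p53 list had 2 of 25 higher, or 4 adjusted over the list alone (camera adjusted p = 0.000219, adjusted p = 0.081 with an estimated correlation). Glycolysis and hypoxia had 0 of 26, or 9 higher adjusted over the list alone (camera adjusted p = 4.42e-06, adjusted p = 0.081 with an estimated correlation). Class I antigen presentation had 0 of 24, or 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.53 with an estimated correlation), and the unfolded protein response 0 of 23, or 1 higher adjusted over the list alone (camera adjusted p = 0.0188, adjusted p = 0.15 with an estimated correlation).

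The lists camera called lower at 100 ng/ml were 4, of which fry did not call the interferon-stimulated (adjusted p = 0.14), the collagen and matrix (0.14) and the collagen processing list (0.12). The interferon-stimulated list had 1 of 40 members lower, or 10 adjusted over the list alone (camera adjusted p = 1.38e-14, adjusted p = 0.25 with an estimated correlation), Gbp7 by 0.68 ± 0.12, lost without untreated replicate 1 (adjusted p = 0.233) and without 5 others. Collagen and matrix genes had 1 of 40 higher, Col5a3 by 0.71 ± 0.08, or 2 higher and 7 lower adjusted over the list alone (camera adjusted p = 4.42e-06, adjusted p = 0.28 with an estimated correlation). The call on Col5a3 was lost without untreated replicate 1 (adjusted p = 0.0614), untreated replicate 2 (0.0707) or TWEAK100 replicate 1 (0.0521). Collagen processing had 0 of 22, or 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00406, adjusted p = 0.28 with an estimated correlation). Lung fibroblast identity had 1 of 33 higher and 3 lower, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.000219, adjusted p = 0.081 with an estimated correlation), with Itga8 falling by 0.81 ± 0.08, Limch1 by 0.77 ± 0.13 and Npnt by 0.60 ± 0.09, and Cd34 rising by 1.48 ± 0.23. Of these, Itga8 alone kept its call whichever library was left out. The 6 lists that camera did not call were matrix proteases (3 of 33 higher, 1 lower), TGF-beta (1 of 31 higher), myofibroblast and contractile (1 of 29 lower), complement and acute phase (1 of 18 higher), cholesterol (0 of 25) and TNF superfamily (0 of 18, called up by fry), with camera adjusted p between 0.253 and 0.74. Adjusted over the list alone these were 5 higher and 4 lower, 4 and 2, 2 and 1, 2 and 1, 0, and 1 higher. Median, mean and camera direction differed in sign for the protease, TGF-beta and myofibroblast lists. Mmp9 (6.26 ± 0.24), Mmp10 (1.19 ± 0.09), Timp1 (0.39 ± 0.05), Timp3 (-0.70 ± 0.08), Ltbp2 (0.93 ± 0.04), Cthrc1 (-1.08 ± 0.18) and C3 (1.26 ± 0.08) were their called members among the named genes, and of these Timp1, Timp3 and Cthrc1 lost the call without untreated replicate 1 (adjusted p = 0.126, 0.0612 and 0.185) and without other libraries.

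**Figure D3:**
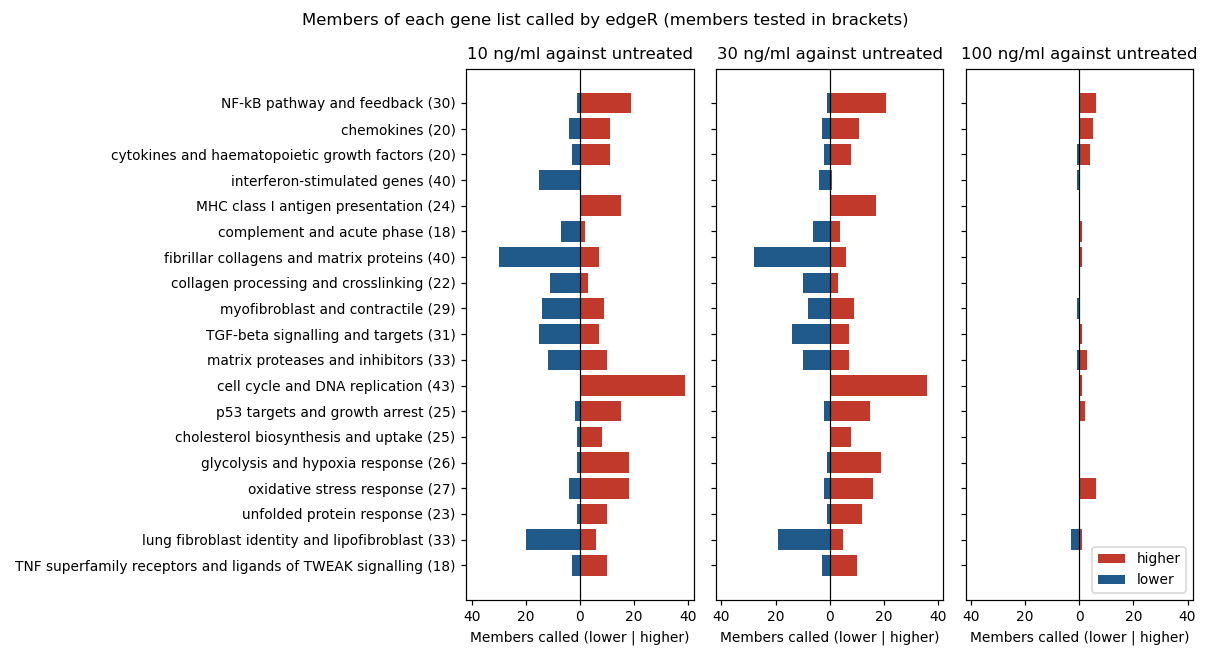
For each of 19 gene lists, bars give the number of members called higher (right) or lower (left) by edgeR at 10, 30 and 100 ng/ml against untreated cells, with the number of members tested in brackets. The cell cycle list had 39 members higher at 10, 36 at 30 and 1 at 100 ng/ml.

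Averaged over the 3 doses, the rises were led by Mmp9, Spib, Traf1, Madcam1, Bst1, Ccl5, Slc39a4, Tlr1, Il2rg and Myh15, and the falls by Acss3, Aspn, Ces1g, Clec3b, Gucy1a3, Lrp4, Ogn, Pcdhgb1, Selenbp1 and St8sia2. The fitted change of Bst1, 6.77, was 11.59 without untreated replicate 2, and those of Madcam1 (7.89) and Slc39a4 (5.60) were 12.70 and 10.87 without untreated replicate 1. In all 4112 genes changed, 2100 higher and 2012 lower. Camera called 15 of the 19 lists, and with an estimated correlation p53 and growth arrest, glycolysis and hypoxia, and lung fibroblast identity, each at adjusted p = 0.043. The number of genes fell to 2193 without untreated replicate 1 and 2315 without untreated replicate 2.

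Between doses, the libraries labelled 100 ng/ml lay closer to untreated cells on the first principal component than the others. Against 10 ng/ml, Mmp9 was lower by 4.84 ± 0.17, Bst1 by 6.22 ± 0.68, Il4i1 by 6.69 ± 0.72 and Colq by 6.06 ± 0.82 on the log2 scale, and Myh15 stood at 0.0752 ± 0.000254 against 27 ± 8.15 CPM. Ces1g was higher by 4.42 ± 0.38, Ogn by 4.20 ± 0.22, Clec3b by 3.97 ± 0.35 and Aspn by 3.92 ± 0.19. Pcdhga2 was also higher (4.97 ± 1.29, edgeR adjusted p = 0.0289), but its 2 libraries at 100 ng/ml differed 22.3-fold and the call was lost without TWEAK100 replicate 1 (log2 change 1.43), TWEAK10 replicate 1 (adjusted p = 0.138) or TWEAK10 replicate 2 (0.142). In all 3816 genes differed between 100 and 10 ng/ml, 1864 higher and 1952 lower at 100, with 2524 without TWEAK10 replicate 1 and 2406 without TWEAK100 replicate 1. Between 100 and 30 ng/ml 2637 genes differed, 1242 higher and 1395 lower, with 1380 without TWEAK30 replicate 1, 1567 without TWEAK100 replicate 1 and 1631 without TWEAK100 replicate 2. Ogn, Aspn, St8sia2, Plagl1 and Peg3 led the rises of that comparison, and Peg3 lost its call without TWEAK30 replicate 1 (edgeR adjusted p = 0.0735). Between 30 and 10 ng/ml edgeR called 0 genes, with 1208 at an unadjusted p under 0.05. DESeq2 called 129 and limma-voom 0. Leaving out 1 library gave 4 genes without untreated replicate 1, 3 without untreated replicate 2, 10 and 9 without TWEAK10 replicate 1 and 2, 62 and 6 without TWEAK30 replicate 1 and 2, and 3 without TWEAK100 replicate 1 or replicate 2. Camera called 16 lists between 100 and 10 ng/ml, 15 between 100 and 30 and 12 between 30 and 10, of which fry called 2. With an estimated correlation it called 0, 2 (p53 and growth arrest, and glycolysis and hypoxia, both lower at 100 ng/ml, adjusted p = 0.045) and 0.

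Genes called at 1 dose were mostly called at another. Of the 194 genes called at 100 ng/ml, 187 were called in the same direction at 10 ng/ml (96.4%), against 21.2 higher and 7.5 lower for independent lists and a mean of 0.05 in 20 simulations of unchanged groups. At 10 and 30 ng/ml 3740 genes were called in the same direction, against 327.6 and 264.4 for independent lists and 0.15 simulated, and at 30 and 100 ng/ml 182, against 17.7 and 5.7 for independent lists and 0.1 simulated. The simulated groups held no changed gene, so few genes could be called in them. Their overlap therefore does not show what the shared untreated libraries add when many genes are called. The covariance of log2 changes was 1.184 between 10 and 30 ng/ml, 0.555 between 10 and 100 and 0.525 between 30 and 100, against 0.122 to 0.123 simulated. The correlations across genes, which are not independent replicates, were 0.829, 0.56 and 0.593, against 0.494, 0.49 and 0.489 simulated. The doses share 2 untreated libraries, too few to split. The simulated doses shared theirs too, so the simulated covariance holds what sharing adds when genes vary independently. Genes that vary together between real libraries were not simulated, so part of the excess may still come from the shared libraries. At all 3 doses 181 genes were called in the same direction, 135 higher and 46 lower, or 94 and 83 by limma-voom, with 82 (75 and 7) without untreated replicate 1, 108 without untreated replicate 2, 84 (73 and 11) without TWEAK100 replicate 1, 104 without TWEAK100 replicate 2 and 512 by DESeq2. The 5 genes called at 100 ng/ml and at neither other dose, chosen after their values were seen, were Plpp5 (log2 change 0.99), Chmp3 (1.12) and Matr3 (0.59), which were higher, and Ing1 (-0.86) and Shisa5 (-0.95), which were lower. Their differences from 10 ng/ml passed the test, with edgeR adjusted p from 0.000264 to 0.0402, as did those from 30 ng/ml, from 0.000677 to 0.0281. These tests reuse the libraries by which the genes were chosen, so they are no separate support. When 1 library was left out, Shisa5 kept the call at 100 ng/ml throughout, while it was lost (adjusted p = 0.058 to 0.264) for Plpp5, Ing1 and Matr3 without untreated replicate 1 or TWEAK100 replicate 2, for these and Chmp3 without untreated replicate 2, for Plpp5, Chmp3 and Matr3 without TWEAK100 replicate 1, for Ing1 without either 10 ng/ml library and for Matr3 without either 30 ng/ml library. The difference from 10 ng/ml was lost for Matr3 without 5 of the 8 libraries, and that from 30 ng/ml for Matr3 without 4 and Ing1 without 2. Chmp3 was called lower at 10 ng/ml without untreated replicate 2 (adjusted p = 0.0405), TWEAK30 replicate 1 (0.0349) or TWEAK30 replicate 2 (0.0364).

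Lymphocyte and red blood cell markers summed to at most 0.793 and 0.176 CPM in any library. Of 11 macrophage markers Cd68 (2.10 ± 0.16), Cd14 (1.22 ± 0.17) and Mrc1 rose at 10 ng/ml, and Ptprc averaged at most 0.325 CPM in any group (camera adjusted p = 0.163). At 100 ng/ml the macrophage list was called higher (camera adjusted p = 0.000335, adjusted p = 0.10 with an estimated correlation), with 1 of 11 members called, Cd68 by 1.19 ± 0.16. The called macrophage markers rose alongside the chemokine, cytokine and NF-kB lists. For no marker list was it tested whether changes came from the fibroblasts or from other cells. Of 9 endothelial markers Cdh5 (4.72 ± 0.34) and Calcrl (2.02 ± 0.10) rose and Tek fell (-1.70 ± 0.25) at 10 ng/ml (camera adjusted p = 0.997), the list having a median of -0.16 and a mean of 0.03. Of 8 mesothelial markers 6 fell at 10 ng/ml, Rspo1 from 12.7 to 2.23 CPM and Upk3b from 6.68 to 2 CPM (camera adjusted p = 0.00169, adjusted p = 0.23 with an estimated correlation), alongside the matrix and lung fibroblast lists. The mesothelial list was also called lower at 30 ng/ml, with 5 of 8 members called (camera adjusted p = 0.000647, adjusted p = 0.20 with an estimated correlation), and at 100 ng/ml, with 0 of 8 (camera adjusted p = 0.0078, adjusted p = 0.20 with an estimated correlation). Of 7 smooth muscle and pericyte markers 2 rose and 3 fell, Rgs5 rising by 3.11 ± 0.47 and Mylk falling (-0.68 ± 0.06) (camera adjusted p = 0.268), and of 5 epithelial markers Ager rose (2.71 ± 0.33) and Hopx fell (-2.87 ± 0.49) (camera adjusted p = 0.703). Ager and Hopx were low, with means of 2.56 and 2.84 CPM over the 8 libraries. Mitochondrially encoded genes held 3.54% to 3.86% of counts. The Y-linked gene Ddx3y had at least 3220 counts and Xist at most 9 counts in each library.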

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

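The depth, mixture, exchanged-label and interferon tests were chosen only after the results were seen. The smaller response in the libraries labelled 100 ng/ml was picked out because the effects of 2 doses differed in a direct test, 3816 genes against 10 ng/ml and 2637 against 30 ng/ml. Of 4112 genes called with the doses averaged, a choice that treats the doses alike, 3986 changed more at 10 than at 100 ng/ml.

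Depth is argued against, since the mean total count at 100 ng/ml was 1.001 times that at 10 ng/ml, with overlapping totals. A mixture of untreated and fully responding RNA would give each gene the same fraction of its change at 10 ng/ml. A first ratio of median fractions, genes raised over 4-fold to genes raised 2- to 4-fold, was 0.722 (95% bootstrap interval 0.611 to 0.852), below 1 but with an interval crossing the bound set for it, and did not decide. A second ratio, chosen because the first did not decide, set genes raised over 4-fold (median fraction 0.135) against genes lowered over 4-fold (0.33). It gave 0.408 (0.343 to 0.496), below the 1 of a plain mixture. Both intervals resampled genes, which share the same libraries, so they leave out variation between libraries. The genes were also chosen by their change at 10 ng/ml, which enters the fraction. The ratio thus argues against a plain mixture for these genes but does not exclude it. An exchange of the 10 and 100 ng/ml labels stays open. Of the genes called with the doses averaged, 79.1% had a change at 30 ng/ml between the others. A response that declines with dose may also give this. In the labels, libraries 1 and 2 were untreated. Libraries 3 and 4 were 100 ng/ml, 5 and 6 were 30 ng/ml, and 7 and 8 were 10 ng/ml. With the 10 and 100 ng/ml labels exchanged, these numbers would rise with dose. So would the distance from untreated libraries on the first principal component. As labelled, the numbers after untreated run from the highest dose to the lowest, also a regular order, so they do not decide.

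The fall of the interferon-stimulated list, with Ifit2 among its members, may reflect variation between libraries of a group. Its mean log2 CPM was 4.33 and 3.53 in the 2 libraries at 30 ng/ml, and that difference was 3.59 times the smallest fall of a dose group. The fall at 10 and 100 ng/ml, 0.74 and 0.70, exceeded the differences of 0.34 and 0.20 within those groups, so an effect of TWEAK on these genes also stays open.

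Rows without a gene symbol, which no comparison used, also moved with treatment. Of 341 such rows tested, 36 were called at 10 ng/ml, 24 higher and 12 lower, 17 at 30 ng/ml and 1 at 100 ng/ml. Of the genes with a symbol 29.2%, 23.3% and 1.1% were called at these doses, a larger share at each. The rows without a symbol were tested in a separate fit and together held at most 0.178% of a library's counts. Power may therefore differ, and the shares do not show a weaker response of these rows.

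Replicates of some genes, such as Pcdhga2, Pcdhgb1 and Peg3, differed over 2-fold, and they were singled out after their values were seen. Of 373 such genes with at least 5 CPM 42.9% had an exon overlapping another gene, against 37% of 10603 others (odds ratio 1.28, 95% interval 1.03 to 1.58, Fisher's exact test p = 0.0254). The test counted genes as independent, but overlapping genes come in pairs or clusters, so its interval may be too narrow and its p too small. Reads shared between overlapping genes may account for some of the genes whose replicates differed, but most had no such overlap.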

How the results depend on the processing

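The thinned, unstable-gene and no-100 ng/ml settings were chosen only after seeing the data. The counts at 10 ng/ml stayed within 1.5 times of 5075 under every alternative run except a log2 change of at least 1, which by construction calls fewer genes: 1919 at 10 ng/ml, 1441 at 30, 89 at 100, 1158 averaged, 802 for 100 against 30, 1249 for 100 against 10 and 85 at all 3 doses. DESeq2 called 598 genes at 100 ng/ml (the 194 of edgeR among them), 129 for 30 against 10 ng/ml and 512 at all 3 doses, and the cause was not tested. Without genes whose replicates differed over 2-fold these were 476, 36 and 420, a setting that removes 3773 genes by the spread the test measures and so raises calls by construction. For 30 against 10 ng/ml, a fit of only the groups compared called 5 genes and one without both libraries labelled 100 ng/ml 3. Camera called 0 lists at 100 ng/ml with an estimated correlation, against 13 with the preset one. Thinning all libraries to the lowest total gave 5012 genes at 10 ng/ml, 194 at 100 and 3807 for 100 against 10 ng/ml, against 5075, 194 and 3816. The median log2 change of all genes did not exceed 0.036 in size under any scaling.

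Leaving out 1 library gave 3392 to 4839 genes at 10 ng/ml, 2540 to 3831 at 30, 91 to 237 at 100, 2193 to 3792 averaged, 3 to 62 for 30 against 10, 1380 to 2468 for 100 against 30, 2406 to 3545 for 100 against 10, 82 to 212 at all 3 doses and 11 to 14 lists at 100 ng/ml. Fewer libraries leave less power, which does not account for counts above those of all libraries, as at 100 ng/ml and for 30 against 10 ng/ml. Beyond that the cause was not tested. The replicate block gave 4661, 3578 and 136 genes at 10, 30 and 100 ng/ml. Replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated between -0.046 and 0.028.

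Changes of sign were seen in named genes, mostly not called, and the cause was not tested. Without single libraries the log2 change ran from -0.34 to 0.18 for Msmo1 and from -1.70 to 0.60 for Peg3 at 10 ng/ml (Peg3 adjusted p = 0.0443 without untreated replicate 2), from -1.07 to 0.59 for Pcdhga2 at 30 ng/ml, and at 100 ng/ml from -2.26 to 2.15 for Il4i1, -0.15 to 2.15 for Peg3 and -0.10 to 0.10 for Tnfsf12. For Colq, 100 ng/ml against untreated, it ran from -0.44 to 6.96. Pcdhga2 at 30 ng/ml was at 0.02 without TMM and 0.26 with the replicate block, against -0.01, and Tnfsf12 at 100 ng/ml at -0.01 without the low-count filter. Among 2264 values of named genes at 10 ng/ml 2209 kept direction and side of the threshold, among 2264 at 30 ng/ml 2205, and among 2148 at 100 ng/ml 1861, with 155 losing and 126 gaining the call. Depth limits genes near 3 counts over a group, such as Traf1, Ngfr and Myh15, whose folds are ratios or lower bounds.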

Other observations

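Both list tests here were chosen after the results were seen. Several genes known from the stroma of lymphoid organs rose, namely Madcam1, Spib, Bst1 and Tnfsf11, and a hypothesis is that such genes rise as a group. Of 14 other members of a list of lymphoid organiser genes, left after these 4 were taken out, 8 rose and 3 fell at 10 ng/ml (camera p = 0.000208, p = 0.0928 with an estimated correlation). At 100 ng/ml 5 rose and edgeR called 0 lower (camera p = 2.01e-05, p = 0.0652 with an estimated correlation). The list shares genes with the NF-kB, chemokine and cytokine lists, so it may not be separate from them, and the test at 10 ng/ml left the hypothesis open.

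The falls of Sfrp2, Lrp4 and Nkd1 led to the hypothesis that Wnt targets and antagonists may fall as a group. Of 20 other members, left after these 3 were taken out, 10 fell and 2 rose at 10 ng/ml (camera p = 0.00186, p = 0.0558 with an estimated correlation). At 30 ng/ml 9 fell and 1 rose (camera p = 0.00037, p = 0.0404 with an estimated correlation). At 100 ng/ml 1 fell (camera p = 0.0125, p = 0.1 with an estimated correlation). Nkd1 is also on the lung fibroblast identity list, which camera called lower at 10 ng/ml. The Wnt list may therefore not be separate from it, and the test at 10 ng/ml left this hypothesis open too.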
